A study of Rattus norvegicus with 45 samples.

How the data were processed

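RNA from 8 tissues of male spontaneously hypertensive rats was sequenced on a BGISEQ-500 with single-end reads of 50 bases, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and the rat genome build Rnor_6.0; the counting program is not given in the sources used here. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene and library, with 2 decimals, as made by the authors. All 45 libraries were used, with 20794 genes listed as mRNA, of which 276 were at 0 in every library. Gene symbols come from the same tables, and 27 symbols belong to more than 1 identifier. Of the tissue labels, that of the libraries labelled V disagrees with the series design, which names ventricle. Groups were formed from tissue and arm as the labels give them, 3 libraries each, which the design describes as 3 rats per arm. No vehicle atrium library was analysed here.

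FPKM are not counts, so the total reads per library are unknown and no count test or counting interval was made. In 567 genes with low values the steps between values were read as whole reads. That 81.2% of values lay within 15% of a whole read is no test of this, as values of many reads must. These steps gave the relative value of 1 read per library, 0.909 to 1.29, and no absolute depth without gene lengths. Values over 1.5 times a gene's lowest were left out, which bounds the range. A change in a few abundant transcripts moves every other FPKM of a library, because FPKM are relative to the total. Reads shared by near-identical genes, and by overlapping genes on opposite strands, cannot be told apart here, since the counting is not described. Of the genes, 20 alternated between 0 and at least 5 FPKM within at least 5 of the 15 groups, and a 0 in these tables can be a failed estimate.

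Each tissue was tested alone, 3 vehicle against 3 empagliflozin libraries, with limma 3.58.1 in R 4.3.3 (linear model with an intensity trend and empirical Bayes moderation) on log2(FPKM + 1), over genes with a mean of at least 1 FPKM in at least 1 arm. Fold changes on this scale understate the change of genes with low values. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05 and are those of limma and two-sided. Of 63 gene lists, 29 of processes and 34 of cell type markers, those with at least 4 genes tested were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted within a tissue. In all 7 tissues 0 lists passed with an estimated correlation, and 0 with fry, which asks whether the genes of a list move on balance in 1 direction. Members were also adjusted over the list alone. The difference between tissues was an arm by tissue term in 1 model, each tissue against the mean of the others. This model estimates 1 spread per gene over all tissues, not the spread within each tissue, and so does the fit of all tissues at once. The tests, the gene lists and the rule for named genes were fixed before the data were examined. By that rule, a tissue names its called genes with a proper symbol, up to 12 per direction, or the 3 with the lowest p per direction where none was called, the 4 members with the lowest p of each called list, and a panel of genes of glucose, lipid, natriuretic and clock biology. The results of some named genes are not reported here.

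Alternatives were quantile normalization, median-ratio scaling, robust empirical Bayes, a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, all tissues in 1 fit, the replicate number as a block, the animal as a random effect in the model of all tissues, and each library left out in turn. The aorta without the libraries numbered 1, the list tests under these settings, 1 weight per tissue, leaving out a number in all tissues, the block in lung in the model of all tissues, and the list tests of the difference under these were chosen after seeing the data. The replicate numbers come from the sample titles. In lung, deviations from the arm means correlated across genes within each pair of the same number (r = 0.227, 0.303 and 0.346). There 6 of 6 libraries correlated best with their own number, so the lung numbers were treated as pairs. The arms are different rats, and this pairing was read from the same data that it was applied to. It was not tested against chance, and no other tissue showed such a match. With that block 0 genes passed in lung (1768 at an unadjusted p under 0.05), and 19 lists, 17 of them shared with the 17 called without it.

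The tests were checked on simulated data with 200 changed genes per tissue. Of genes changed by 1 on the log2 scale, limma found 81% in kidney, 0% in aorta, 45% in brain, 79% in brown fat, 24% in white fat, 88% in lung and 94% in the libraries labelled V. Of those changed by 2 it found 98%, 0%, 89%, 100%, 98%, 97% and 99%. Of 10 lists shifted by 0.5, camera found 9 in aorta and 10 in each other tissue, and 0 of 10 unshifted lists were called. It found 0 in aorta and 10 in each other tissue with an estimated correlation. Simulated genes were independent, whereas in the data the estimated correlation was 0.976 for podocyte markers in kidney and 0.981 for neuron markers in aorta. These counts therefore do not give the error rate or power of camera for correlated lists. Unchanged genes made up 17 of 196 calls of limma in kidney, 5 of 139 in brain, 7 of 186 in brown fat, 9 of 131 in white fat, 11 of 196 in lung and 17 of 210 in the libraries labelled V, with 0 calls in aorta. For the difference between tissues, simulated in kidney over 16822 genes, 92.5% of 200 genes changed by 2 were found, along with 12 unchanged genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.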

Results

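Messenger RNA was sequenced from 8 tissues of male spontaneously hypertensive rats, an inbred strain that develops high blood pressure. The rats were 8 weeks old and weighed 220 to 260 g. They received empagliflozin, an inhibitor of the renal sodium-glucose cotransporter SGLT2 used in type 2 diabetes and heart failure, by gavage at 10 mg/kg per day, or saline vehicle, for 30 days. The series compared the transcriptional response across tissues. It held 45 libraries in 15 groups of 3, with 21 vehicle and 24 empagliflozin libraries. In 7 tissues both arms were present: kidney, aorta, brain, brown fat, white fat, lung and a tissue whose libraries carry the letter V in their titles. Atrium was represented by 3 empagliflozin libraries, and vehicle atrium was not analysed here. The labels of the V libraries name liver, whereas the description of the series names ventricle, so they are called the libraries labelled V throughout. In these 6 libraries the mean level of cardiomyocyte markers exceeded that of hepatocyte markers by 9.43 ± 0.39 (SD, n = 6) on the log2 scale.

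Values were deposited as FPKM, fragments per kilobase scaled to the mapped fragments of a library, for 20794 genes, so total read counts per library are unknown. The sum of FPKM per library ranged from 414248 to 824205. The value that 1 read is worth, relative to the median of each gene's lowest values, lay between 0.909 and 1.29. Only values within 1.5 times a gene's lowest were used, so this bounded range cannot show whether depth differed. In vehicle aorta library 1 and empagliflozin brown fat library 3 the value rested on 3 genes. Of the 45 libraries, 43 correlated best with another library of their own tissue. The exceptions were vehicle aorta library 1, closest to vehicle brown fat library 2 (Pearson r = 0.981 across genes), and empagliflozin aorta library 1, closest to vehicle brown fat library 1 (r = 0.986). Genes are not independent replicates, and these correlations describe similarity only. Fold changes are differences of log2(FPKM + 1), empagliflozin minus vehicle, of 3 libraries per arm. The median of all genes was shifted by 0.10 in kidney, 0.18 in aorta and -0.18 in white fat. Changes there are relative to it, but gene p-values and counts of members higher or lower are not. A permutation of 3 against 3 libraries cannot give a p below 0.1.

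In kidney, transcripts of sodium and water transport and of podocytes were higher with empagliflozin and those of the proximal tubule, the segment in which SGLT2 is expressed, were lower. The list of renal sodium and water transport genes rose, with 20 of 27 members higher and a median log2 change of 0.73. Adjusted over the list alone, 6 members rose, among them Kcnj1 (0.89 ± 0.19, SE), the potassium channel of the thick ascending limb and collecting duct, Klhl3 (1.64 ± 0.42), a regulator of the thiazide-sensitive cotransporter and Aqp4 (1.78 ± 0.42), a water channel. Loop to collecting duct markers were higher in 9 of 11 members (median 0.82), but the list was not called (adjusted p = 0.0623). All 6 podocyte markers were higher (list median 1.14), with Podxl, a sialomucin of foot processes, at 1.17 ± 0.45. Proximal tubule markers fell as a list, with 10 of 11 members lower and a median of -0.59. Slc22a6, an organic anion transporter, changed by -0.56 ± 0.17, and Lrp2, the endocytic receptor megalin, by -0.61 ± 0.27. Slc5a2, which encodes SGLT2, was at 1.86 ± 1.52 FPKM in vehicle and 2.51 ± 2.82 FPKM in empagliflozin libraries (SD, n = 3), a relative log2 change of 0.03 ± 0.60.

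The camera test gave adjusted p = 0.00736 for the transport list, 0.0106 for podocyte markers and 0.000387 for proximal tubule markers, and adjusted p = 0.699 with an estimated correlation for each. The podocyte call was lost without vehicle library 2 (adjusted p = 0.0557). Without empagliflozin library 3 the calls stayed, but before centring the podocyte median was 0.801 instead of 1.247 and the proximal tubule median -0.32 instead of -0.49. The podocyte level was 4.32, 3.64 and 5.23 in empagliflozin libraries 1, 2 and 3 and 2.45, 2.94 and 3.99 in vehicle libraries, on the log2 scale.

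**Figure D1:**
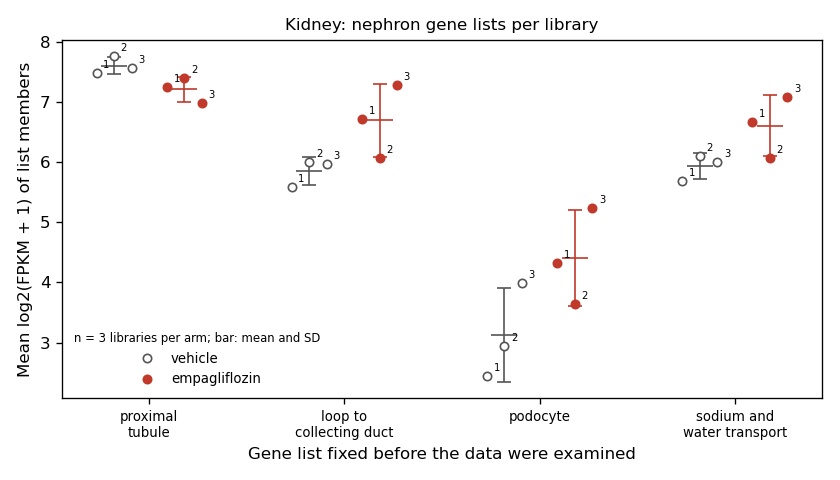
Level of 4 nephron gene lists in each kidney library, as the mean log2(FPKM + 1) of the list members on the vertical axis and the list on the horizontal axis. Open grey circles are vehicle and filled red circles empagliflozin libraries with their replicate number, and bars give the mean and SD (n = 3); the podocyte level of empagliflozin library 2, 3.64, lies below that of vehicle library 3, 3.99.

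Further lists rose in kidney. Interferon response genes were higher in 29 of 30 members (median 0.40, adjusted p = 0.000387). Cell cycle genes were higher in 18 of 18 members (median 0.40, adjusted p = 0.000318), with Top2a, a topoisomerase of dividing cells, at 0.83 ± 0.24, and this call was lost when a mean of at least 5 FPKM was required (adjusted p = 0.0834). Respiratory chain genes rose by a median of 0.09 (adjusted p = 0.000782), and endothelial markers by 0.52 (adjusted p = 0.0319). Glycolysis genes rose by a median of 0.24 (adjusted p = 0.0438), and 8 of 20 rose adjusted over the list alone, including Pfkp (0.73 ± 0.17) and Pkm (0.67 ± 0.19), both enzymes of glycolysis. Cholesterol synthesis genes rose by a median of 0.09 (adjusted p = 0.0106). Of these 22 genes, 3 rose adjusted over the list alone, among them Cyp51 by 0.50 ± 0.11 and Hmgcs1 by 0.46 ± 0.15, both enzymes of sterol synthesis. With an estimated correlation the adjusted p = 0.701 for glycolysis and adjusted p = 0.699 for the others. The endothelial call was lost without vehicle library 2 (adjusted p = 0.0557) or empagliflozin library 2 (0.0595), the cholesterol call without vehicle library 2 (0.0886) or empagliflozin library 2 (0.378), and the glycolysis call without vehicle library 3 (0.0806) or empagliflozin library 1 (0.215). Where the calls stayed, the endothelial median before centring was 0.35 without empagliflozin library 3 instead of 0.63, and that of glycolysis 0.22 without vehicle library 1 or empagliflozin library 3 instead of 0.34. With all tissues in 1 fit the calls of the respiratory chain (adjusted p = 0.951), cholesterol synthesis (0.346) and glycolysis (0.250) were lost. The glycolysis call was also lost without a filter on low values (0.0641) and with the replicate number as a block (0.0550). Under quantile normalization the median was 0.22 for the respiratory chain and 0.38 for glycolysis.

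Other lists fell in kidney. Fatty acid oxidation genes were lower in 23 of 33 members (median -0.22, adjusted p = 0.000387), although the member that passed adjusted over the list alone, the fatty acid binding protein gene Fabp3, was higher (1.10 ± 0.22). Gluconeogenesis genes fell by a median of 0.43 (adjusted p = 0.0369), with Pck1, which commits to glucose formation, at -0.94 ± 0.30. Fibroblast markers (-0.53, adjusted p = 0.0195), smooth muscle markers (-0.59, adjusted p = 0.00677), cardiomyocyte markers (-0.45, adjusted p = 0.0229) and ribosomal protein genes (-0.12, adjusted p = 0.0379, lost under quantile normalization with adjusted p = 0.953 and a median of 0.03) fell too. Vehicle library 2 held fat transcripts: 19 of 19 abundant white fat genes were higher in it than in each other kidney library, at a median of 0.267% of their white fat level against 0.0201% to 0.0401%, and so were 10 of 11 brown fat genes (0.271%). For ribosomal proteins adjusted p = 0.780 with an estimated correlation, and for the others adjusted p = 0.699. The gluconeogenesis, fibroblast and cardiomyocyte calls were lost under median-ratio scaling (adjusted p = 0.0736, 0.0910 and 0.0895) and quantile normalization (0.171, 0.0553 and 0.0571), the smooth muscle and ribosomal protein calls without vehicle library 2 (0.235 and 0.999), and the gluconeogenesis and fibroblast calls also without that library (0.0512 and 0.174). Without empagliflozin library 2 the smooth muscle and gluconeogenesis calls were lost (0.0595 and 0.0914), without empagliflozin library 3 those of gluconeogenesis (0.0527) and ribosomal proteins (0.564), and without empagliflozin library 1 that of fibroblasts (0.0788). The cardiomyocyte call was lost without vehicle library 1 (0.380), vehicle library 2 (0.0512) or empagliflozin library 1 (0.376). The calls of gluconeogenesis, fibroblasts, smooth muscle, cardiomyocytes and ribosomal proteins were also lost with all tissues in 1 fit (0.158, 0.158, 0.136, 0.116 and 0.160) and with a mean of at least 5 FPKM (0.0603, 0.281, 0.0834, 0.0964 and 0.0634), and those of cardiomyocytes (0.0641) and ribosomal proteins (0.0727) without a filter. Medians before centring also moved where calls stayed. That of smooth muscle was -1.01, -0.32 and -0.92 without vehicle library 1 and empagliflozin libraries 1 and 3, instead of -0.49, and that of fibroblasts -0.67 without vehicle library 1, instead of -0.42. The cardiomyocyte median was -0.68, -0.54 and -0.59 without vehicle library 3 and empagliflozin libraries 2 and 3, instead of -0.35. That of fatty acid oxidation was -0.053 and -0.19 without vehicle libraries 2 and 3, instead of -0.12, and that of ribosomal proteins -0.088, -0.072 and -0.059 without vehicle libraries 1 and 3 and empagliflozin library 1, instead of -0.020.

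With limma, 0 of 12848 genes passed in kidney (smallest adjusted p = 0.131), and 1504 had an unadjusted p under 0.05, 1088 higher and 416 lower. The share of these that were higher, 72.3%, was 56.7% after median-ratio scaling. The gene with the lowest p was Spp1, which encodes the secreted phosphoprotein osteopontin, at 93.5 ± 8.97 FPKM in vehicle and 313 ± 55.5 FPKM in empagliflozin libraries (SD, n = 3). Of all genes 19.1% had arms that did not overlap, against 10% by chance. Another split, vehicle libraries 1 and 3 with empagliflozin library 2 against the others, gave 3134 genes at an unadjusted p under 0.05 (limma). The 1504 genes therefore do not single out the arm, and the share of 19.1% was not computed for other splits. Without empagliflozin library 2, 636 genes passed (541 higher, 95 lower), without vehicle library 2, 1, and with all tissues in 1 fit, 209. The count of 15 lists was 8 without vehicle library 2.

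In white fat, transcripts of fatty acid synthesis were higher with empagliflozin. The lipogenesis list rose, with 21 of 22 members higher and a median log2 change of 1.32, and 13 members rose adjusted over the list alone. Fasn, the fatty acid synthase, went from 167 ± 107 to 1019 ± 206 FPKM (SD, n = 3; log2 change 2.99 ± 0.50, SE), and Scd, a stearoyl-CoA desaturase, from 597 ± 470 to 4249 ± 1665 FPKM (3.31 ± 0.71). Pnpla3, a lipid droplet acyl hydrolase (2.70 ± 0.36), and Gpam, which starts glycerolipid synthesis (1.33 ± 0.22), rose as well. Camera gave adjusted p = 2.26e-19 for the list, and adjusted p = 0.490 with an estimated correlation. Adipocyte markers, none of which is in that list, had a median of 0.08.

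Respiratory chain genes rose in white fat, in 38 of 38 members (median 0.91, adjusted p = 2.39e-19), as did fatty acid oxidation genes (0.84, 1.05e-10), although Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, was at -0.95 ± 0.37. Cholesterol synthesis genes rose by a median of 0.67 (adjusted p = 3.89e-13), among them Insig1, a sterol-responsive regulator, by 1.71 ± 0.29 adjusted over the list alone. Thermogenesis genes (0.997, adjusted p = 7.26e-06), heat shock genes (0.64, 7.44e-05), glycolysis genes (0.62, 0.000139), ribosomal protein genes (0.39, 5.07e-05) and brown adipocyte markers (1.05, 0.000264) rose too. With an estimated correlation the adjusted p = 0.490 for cholesterol synthesis, adjusted p = 0.751 for ribosomal proteins and adjusted p = 0.499 for the others. The level of brown adipocyte markers was 3.96 in empagliflozin library 3 and between 1.10 and 1.56 in the other 5 libraries. Without that library the calls of glycolysis (adjusted p = 0.0709), brown adipocyte markers (0.857) and ribosomal proteins (0.105) were lost, the last with an uncentred median of -0.20. The other calls stayed without it, but before centring the median was 0.23 instead of 0.74 for the respiratory chain, 0.16 instead of 0.66 for fatty acid oxidation, 0.25 instead of 0.82 for thermogenesis and 0.039 instead of 0.46 for heat shock genes. The brown adipocyte median before centring was 2.09 and 1.66 without empagliflozin libraries 1 and 2, instead of 0.87, and that of ribosomal proteins 0.49 and 0.36 without these and 0.10 without vehicle library 1, instead of 0.21. The ribosomal protein call was also lost under quantile normalization (adjusted p = 0.577), which gave medians of 0.54 for the respiratory chain, 0.34 for heat shock and 0.26 for glycolysis. With a pseudocount of 0.1 the brown adipocyte median was 1.41 before centring.

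Mesothelial markers rose in white fat, in 7 of 7 members (median 2.39, adjusted p = 1.12e-07), and 6 of them rose adjusted over the list alone, including Upk3b, a uroplakin of mesothelial cells, by 3.15 ± 0.87. The mesothelial level was 0.87 in vehicle library 3, against 3.05 and 3.52 in the other vehicle libraries and 4.11 to 4.62 with empagliflozin, and without that library the median before centring was 1.38 instead of 2.21. Alveolar type 2 markers, which are lung transcripts, were at 3.43 and 2.93 in empagliflozin libraries 1 and 2 and at 1.27 to 1.89 in the other 4 white fat libraries. Neutrophil and mast cell markers rose by 0.67 (adjusted p = 6.08e-05), with Cpa3, a mast cell carboxypeptidase, up by 1.56 ± 0.36 adjusted over the list alone. Adrenal cortex markers rose (median 0.41, adjusted p = 0.0268), carried by Star, the steroidogenic acute regulatory protein, up by 2.23 ± 0.24 adjusted over the list alone. Matrix genes (-0.45, adjusted p = 0.000183), fibroblast markers (-0.75, 0.0123), macrophage markers (-0.67, 0.0205) and glucocorticoid response genes (-0.27, 0.0449) fell. Among these, Loxl1, a collagen crosslinking enzyme, fell by 1.14 ± 0.26 and Dcn, the proteoglycan decorin, fell by 0.75 ± 0.20 adjusted over the list alone, and Itgax, an integrin of myeloid cells, was at -1.60 ± 0.49. With an estimated correlation the adjusted p = 0.536 for matrix and fibroblasts, adjusted p = 0.751 for macrophages, adjusted p = 0.615 for glucocorticoid response and adjusted p = 0.499 for the lists that rose. Without vehicle library 2 the calls of matrix (adjusted p = 0.0573), fibroblasts (0.131), macrophages (0.0641) and glucocorticoid response (0.391) were lost, and without empagliflozin library 3 that of macrophages (0.141). The glucocorticoid call was also lost without empagliflozin library 1 (0.137) or 2 (0.344), and the adrenal call without vehicle library 3 (0.0559), empagliflozin library 1 (0.0937) or 2 (0.0501) and under quantile normalization (0.0988). Where calls stayed, the adrenal median before centring was 0.15, 0.54 and 0.37 without vehicle libraries 1 and 2 and empagliflozin library 3, instead of 0.23, and the neutrophil and mast cell median 0.85 and 0.29 without empagliflozin libraries 2 and 3, instead of 0.49. The fibroblast median was -0.38 without empagliflozin library 3 instead of -0.92, the macrophage median -0.41 without vehicle library 3 instead of -0.84, and the glucocorticoid median -0.69 without vehicle library 1 instead of -0.45. All tissues in 1 fit ended the calls of matrix (0.0668), fibroblasts (0.398) and glucocorticoid response (0.625). Without a filter on low values the adrenal call was lost (0.0664) and the neutrophil and mast cell median was 0.25 before centring.

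**Figure D2:**
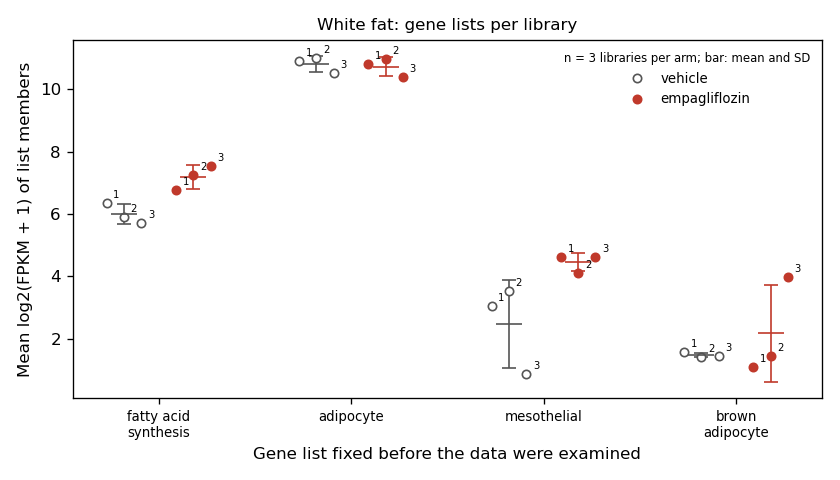
Level of 4 gene lists in each white fat library, as the mean log2(FPKM + 1) of the list members on the vertical axis and the list on the horizontal axis. Open grey circles are vehicle and filled red circles empagliflozin libraries with their replicate number, and bars give the mean and SD (n = 3); brown adipocyte markers reach 3.96 in empagliflozin library 3 alone.

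With limma, 1 of 12740 genes passed in white fat. Wbp11l1 was listed at 9.64, 12.22 and 8.84 FPKM in the vehicle libraries and at 0 in all empagliflozin libraries (adjusted p = 0.00469). It belongs to 20 genes that alternate between 0 and at least 5 FPKM within at least 5 of the 15 groups, so it is said only to be listed at 0. At an unadjusted p under 0.05 there were 1106 genes, 339 higher and 767 lower, and the share that were higher, 30.7%, was 48.4% after median-ratio scaling. Another split of these libraries gave 1586 genes at that threshold, so the 1106 do not single out the arm. Non-overlapping arms were seen in 17.2% of genes, against 10% by chance. The count was 0 without vehicle library 1 or empagliflozin library 2 and with a mean of at least 5 FPKM, 4 without empagliflozin library 3 (Wbp11l1 and the lung transcripts Sftpb, Scgb1a1 and Sftpc), and 121 with all tissues in 1 fit.

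In lung, cell cycle transcripts were lower and mesothelial transcripts higher with empagliflozin. The cell cycle list fell, with 20 of 22 members lower and a median log2 change of -0.84 (adjusted p = 3.1e-13), and 13 members fell adjusted over the list alone. They include Rrm2, a ribonucleotide reductase subunit (-1.54 ± 0.41, SE), Cdk1, the mitotic kinase (-1.26 ± 0.28), and Tyms, the thymidylate synthase (-0.67 ± 0.14). Mesothelial markers rose in 7 of 7 members (median 1.79, adjusted p = 1.6e-07), all 7 adjusted over the list alone, with Msln, the surface protein mesothelin, at 1.90 ± 0.34. For both lists adjusted p = 0.747 with an estimated correlation. The mesothelial median was 2.74 with a pseudocount of 0.1. Vehicle library 3 lay nearest the empagliflozin libraries in both: its cell cycle level was 2.60, against 3.45 and 3.71 in the other vehicle libraries and 2.26 to 2.68 with empagliflozin, and its mesothelial level was 3.80, against 2.08 and 2.01 and 4.20 to 4.79.

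In lung, inflammation, MHC class II, T cell, microglia and macrophage lists fell, while the interferon response (adjusted p = 0.629), B and plasma cell (0.998) and neutrophil and mast cell lists (0.485) were not called. Inflammation genes were lower in 23 of 28 members (median -0.32, adjusted p = 7.09e-05), and Lcn2, the iron-trapping protein lipocalin 2 (-2.32 ± 0.52), and Ccl4, a chemokine (-0.78 ± 0.18), fell adjusted over the list alone. MHC class II genes, which present antigen, were lower in 9 of 9 members (-0.40, adjusted p = 0.00191), with Ctss, a lysosomal protease, at -0.54 ± 0.09 and falling adjusted over the list alone. T cell markers were lower in 10 of 10 members (-0.42, 0.000247), with the CD8 chain gene Cd8b at -0.86 ± 0.24. Microglia markers, shared with tissue macrophages, had a median of -0.42 (adjusted p = 0.00921) and macrophage markers of -0.24 (0.0145). Erythroid markers (-0.68, 0.000996) and glucocorticoid response genes (-0.15, 0.0253) fell as well. Adjusted over the list alone, 3 erythroid markers fell, including the globin gene Hbb (-0.73 ± 0.18), and Ahsp, a globin chaperone, rose (0.99 ± 0.31). Each list that fell here had adjusted p = 0.747 with an estimated correlation. The macrophage call was lost without empagliflozin library 2 (adjusted p = 0.109), and the glucocorticoid call without vehicle library 3 (0.681), empagliflozin library 1 (0.06004) or 2 (0.109) and under quantile normalization (0.0681). With all tissues in 1 fit the macrophage (0.0661) and erythroid calls (0.0661) were lost, and with a mean of at least 5 FPKM the erythroid median was -0.45. The inflammation, MHC class II, T cell, microglia and erythroid calls were not lost without any 1 library, but medians moved. Without vehicle libraries 1, 2 and 3 and empagliflozin library 3, the MHC class II median was -0.22, -0.095, -0.91 and -0.22, the microglia median -0.26, -0.061, -0.96 and -0.21, and the T cell median -0.23, -0.26, -0.86 and -0.27 (highest adjusted p = 0.0480). Without vehicle library 2 the inflammation median was -0.11. The macrophage median was -0.14 and -0.15 without vehicle libraries 1 and 2, and that of glucocorticoid response -0.47 and -0.33 without vehicle library 1 and empagliflozin library 3.

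Ribosomal protein genes (-0.21, adjusted p = 2.18e-06), cholesterol synthesis genes (-0.26, 0.000247), respiratory chain genes (-0.10, 0.000286), alveolar type 2 markers (-0.26, 0.00791) and glycolysis genes (-0.17, 0.0253) fell in lung. Endothelial markers (0.48, adjusted p = 0.00476), club and ciliated cell markers (0.70, 0.0114) and immediate early genes (0.30, 0.0159) rose, with Egr1, an early growth response factor, at 1.08 ± 0.39. With an estimated correlation the adjusted p = 0.756 for the respiratory chain and adjusted p = 0.747 for the others. Without vehicle library 1 the calls of cholesterol synthesis (adjusted p = 0.672), glycolysis (0.120), immediate early genes (0.123), endothelial (0.123) and alveolar type 2 markers (0.152) were lost, and without vehicle library 3 that of club and ciliated cells (0.286). The glycolysis call was also lost without vehicle library 2 (0.0902), empagliflozin library 2 (0.107) or 3 (0.119), the alveolar call without empagliflozin library 2 (0.145) and the immediate early call without empagliflozin library 3 (0.510). Quantile normalization ended the calls of ribosomal proteins (0.189, median -0.062), glycolysis (0.0681) and alveolar type 2 markers (0.148). Without vehicle library 3 the medians were -0.36 for ribosomal proteins, -0.39 for cholesterol synthesis, -0.19 for the respiratory chain, 0.83 for endothelial markers and 0.45 for immediate early genes. The respiratory chain median was -0.057 and -0.040 without vehicle libraries 1 and 2, and the ribosomal protein median -0.14 without vehicle library 1. All tissues in 1 fit ended the calls of the respiratory chain (0.256), glycolysis (0.262) and immediate early genes (0.276). Without a filter on low values those of glycolysis (0.102) and alveolar type 2 markers (0.0534) were lost, and the immediate early median was 0.17.

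**Figure D3:**
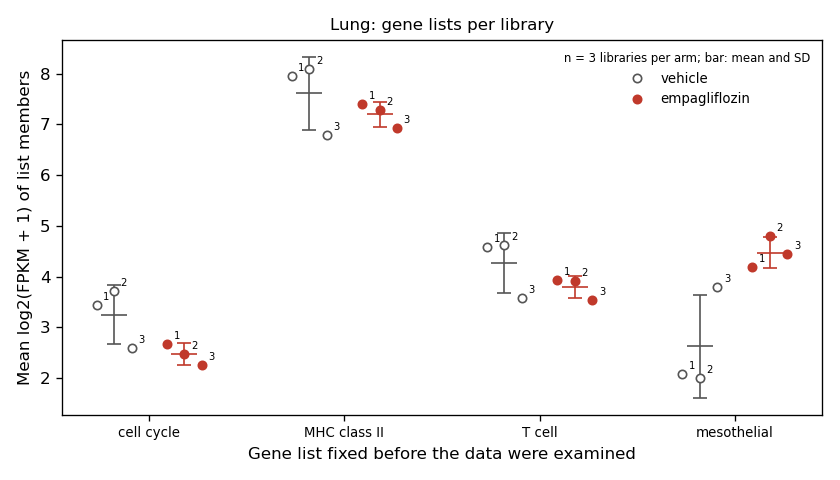
Level of 4 gene lists in each lung library, as the mean log2(FPKM + 1) of the list members on the vertical axis and the list on the horizontal axis. Open grey circles are vehicle and filled red circles empagliflozin libraries with their replicate number, and bars give the mean and SD (n = 3); vehicle library 3 has a cell cycle level of 2.60 and a mesothelial level of 3.80.

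With limma, 0 of 14161 genes passed in lung (smallest adjusted p = 0.198), and 1079 had an unadjusted p under 0.05, 650 higher and 429 lower. The share that were higher, 60.2%, was 48.5% after median-ratio scaling. The lowest p belonged to Steap4, a metalloreductase (1.47 ± 0.15, SE), and Mcpt2, a mast cell protease (1.39 ± 0.14). Another split of these libraries gave 1897 genes at an unadjusted p under 0.05, so the 1079 do not single out the arm. Non-overlapping arms were seen in 12.9% of genes, against 10% by chance. In empagliflozin library 1, 20 of 25 abundant genes of the libraries labelled V exceeded each other lung library, at a median of 0.228% of their level there. Without vehicle library 3, 51 genes passed (30 higher, 21 lower), and with all tissues in 1 fit, 213.

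In brown fat, lipid synthesis transcripts were higher and respiratory chain transcripts lower with empagliflozin. The lipogenesis list rose (18 of 22 members higher, median log2 change 0.24, adjusted p = 6.24e-06), and 4 members rose adjusted over the list alone. These were Scd2, a desaturase (1.61 ± 0.24, SE), Fads1, a fatty acid desaturase (0.94 ± 0.20), Slc25a1, the mitochondrial citrate carrier (0.69 ± 0.17), and Acly (0.79 ± 0.23). Cholesterol synthesis genes rose by a median of 0.31 (adjusted p = 1.62e-05), immediate early genes by 0.35 (0.000864) and interferon response genes by 0.19 (0.0356). Respiratory chain genes fell in 38 of 39 members (-0.25, adjusted p = 5.26e-11), fatty acid oxidation genes (median -0.14, 9.21e-06), ribosomal protein genes (median -0.10, 0.000801, with the direction turned under quantile normalization at a median of 0.01) and glucocorticoid response genes (median -0.17, 0.0204).

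Smooth muscle markers fell in brown fat (median -1.02, adjusted p = 0.000188), and their level was 5.32 in vehicle library 3 and 3.43 to 3.99 in the other 5 libraries. The brown adipocyte gene Ucp1, which uncouples respiration to give heat, was at 7292 ± 2644 FPKM in vehicle and 5916 ± 1274 FPKM in empagliflozin libraries (SD, n = 3). With an estimated correlation the adjusted p = 0.619 for fatty acid oxidation, adjusted p = 0.681 for cholesterol synthesis and adjusted p = 0.961 for the other lists of brown fat. The respiratory chain call was lost without vehicle library 2 (adjusted p = 0.367), and so were those of ribosomal proteins (0.636, median 0.03) and interferon response (0.309). The interferon call was also lost without vehicle library 3 (0.240) or empagliflozin library 1 (0.548), the ribosomal protein call without empagliflozin library 3 (0.232), the immediate early call without vehicle library 1 (0.318) and the glucocorticoid call without vehicle library 3 (0.466) or empagliflozin library 2 (0.398). Quantile normalization ended the calls of fatty acid oxidation (0.171, median -0.053) and glucocorticoid response (0.136), as well as that of ribosomal proteins (0.904). Without vehicle library 3 the medians were -0.44 for the respiratory chain and -0.40 for smooth muscle markers. Without vehicle library 1 they were 0.37 for lipogenesis, 0.29 for interferon response, -0.43 for glucocorticoid response and -0.24 for ribosomal proteins. The glucocorticoid median was -0.28 and -0.33 without vehicle library 2 and empagliflozin library 3, and the interferon median 0.30 and 0.29 without empagliflozin libraries 2 and 3. That of immediate early genes was 0.57 without empagliflozin library 3 and that of ribosomal proteins -0.20 without empagliflozin library 2. All tissues in 1 fit ended the calls of interferon response (0.0673) and immediate early genes (0.0582), a mean of at least 5 FPKM that of interferon response (0.0623), and no filter on low values that of glucocorticoid response (0.0550). The respiratory chain median was -0.11 under quantile normalization and the ribosomal protein median -0.17 under median-ratio scaling.

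With limma, 1 of 11759 genes passed in brown fat. Mrpl1, which encodes a mitochondrial ribosomal protein, was listed at 0 in all vehicle libraries and at 14.99, 11.06 and 18.18 FPKM with empagliflozin (adjusted p = 0.000688). It is another of the 20 alternating genes. At an unadjusted p under 0.05 there were 419 genes, 280 higher and 139 lower, and the share that were higher, 66.8%, was 48.3% after median-ratio scaling. Non-overlapping arms were seen in 8.39% of genes, against 10% by chance. Without vehicle library 3, 3 genes passed, without empagliflozin library 1, 2, and with all tissues in 1 fit, 0. The count of 9 lists was 15 without vehicle library 3.

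In aorta, libraries differed in the tissue they resembled. Smooth muscle markers were at 4.43, 9.42 and 9.76 in vehicle libraries 1, 2 and 3 and at 5.05, 9.04 and 7.99 in empagliflozin libraries, and brown adipocyte markers at 5.51, 3.54 and 1.90 and at 5.31, 2.71 and 5.14. Schwann cell markers reached 8.43 in empagliflozin library 2, in which 45 of 50 abundant brain genes were higher than in each other aorta library, at a median of 3.73% of their brain level. In vehicle library 2 this held for 44 of 50 abundant kidney genes (0.0949%), and in empagliflozin library 1 for 12 of 13 abundant genes of the libraries labelled V (1.06%). Lipogenesis genes rose (22 of 22 members higher, median log2 change 0.84, adjusted p = 8.83e-06), with Mlxipl, a carbohydrate-responsive transcription factor, at 2.21 ± 0.59 (SE). Lipolysis and adipokine genes rose (0.68, adjusted p = 0.0231), as did erythroid (1.41, 0.00119), neuron (1.90, 0.0275) and Schwann cell markers (1.39, 0.0360). Brown adipocyte markers were highest in vehicle library 1 and empagliflozin libraries 1 and 3. The rise of lipogenesis and lipolysis genes was not separated from this imbalance between the arms.

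Ribosomal protein genes fell in aorta in 30 of 31 members (median -0.72, adjusted p = 6e-18), hepatocyte markers, at a level of 3.35 in vehicle library 2, (median -1.08, 4.96e-06) and MHC class II genes (median -0.76, 1.92e-05). Immediate early (-0.64, adjusted p = 0.000128), matrix (-0.51, 0.0078), inflammation (-0.31, 0.0429) and cell cycle genes (-0.26, 0.0467), and macrophage (-0.52, 0.0467) and smooth muscle markers (-0.65, 0.0467), fell too. Each aortic list had adjusted p = 0.777 with an estimated correlation. Quantile normalization ended the calls of ribosomal proteins (adjusted p = 0.110), matrix (0.247), smooth muscle (0.443) and macrophage (0.0851), and median-ratio scaling those of matrix (0.0801), smooth muscle (0.167), macrophage (0.149), inflammation (0.0953) and cell cycle (0.0677). All tissues in 1 fit ended those of cell cycle (0.0698) and macrophage (0.0750), and a pseudocount of 0.1 that of macrophage (0.0713). The replicate number as a block also ended the cell cycle call (0.067). Without a filter on low values those of inflammation (0.101), smooth muscle (0.101), macrophage (0.0546) and Schwann cell (0.0640) were lost, and with a mean of at least 5 FPKM those of inflammation (0.130), smooth muscle (0.0592) and neuron (0.0563). Leaving out vehicle library 3 ended the calls of lipogenesis (0.296), lipolysis (0.495), erythroid (0.139), neuron (0.213), Schwann cell (0.0865), matrix (0.642), inflammation (0.209), immediate early (0.0865), cell cycle (0.236), smooth muscle (0.565) and macrophage (0.0560). Leaving out vehicle library 2 ended those of lipolysis (0.339), neuron (0.0531), Schwann cell (0.323), matrix (0.970), inflammation (0.831), immediate early (0.323), cell cycle (0.323), smooth muscle (0.601) and macrophage (0.970), and vehicle library 1 those of neuron (0.0995), erythroid (0.0891) and Schwann cell (0.0891). Leaving out empagliflozin library 1 ended those of lipolysis (0.783), matrix (0.466), inflammation (0.377), cell cycle (0.201) and smooth muscle (0.942). Empagliflozin library 2 did so for Schwann cell (0.949), inflammation (0.0541), macrophage (0.800) and MHC class II (0.0809), and empagliflozin library 3 for erythroid (0.127), lipolysis (0.122) and cell cycle (0.0995).

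The aortic medians also moved where calls stayed, and are given here before centring. With all libraries they were 1.02 for lipogenesis, 0.87 for lipolysis, 2.08 for neuron and 1.58 for Schwann cell markers. They were -0.33 for matrix, -0.12 for inflammation, -0.58 for MHC class II, -0.45 for immediate early, -0.077 for cell cycle, -0.90 for hepatocyte, -0.46 for smooth muscle and -0.34 for macrophage lists. Without vehicle library 1 lipogenesis was at 1.88, lipolysis at 1.77, matrix at -1.72, inflammation at -0.50, MHC class II at -1.20, immediate early at -1.51, cell cycle at -0.30, hepatocyte at -1.44, smooth muscle at -2.21 and macrophage at -0.86. Without empagliflozin library 2 lipolysis was at 1.32, matrix at -0.77, immediate early at -0.82, cell cycle at -0.29 and smooth muscle at -1.28. Neuron was at 3.22, Schwann cell at 2.42, macrophage at -0.56 and inflammation at -0.051 without empagliflozin library 3, and Schwann cell at 2.52 and immediate early at -0.25 without empagliflozin library 1. MHC class II was at -0.31 without vehicle library 3. Without the libraries numbered 1 of both arms lipolysis was at 1.37, matrix at -1.06, inflammation at -0.29, MHC class II at -1.32, immediate early at -1.33, cell cycle at -0.25, smooth muscle at -1.09 and macrophage at -0.90. Neuron was at 0.97 without a filter on low values, and lipolysis at 1.08 under quantile normalization.

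**Figure D4:**
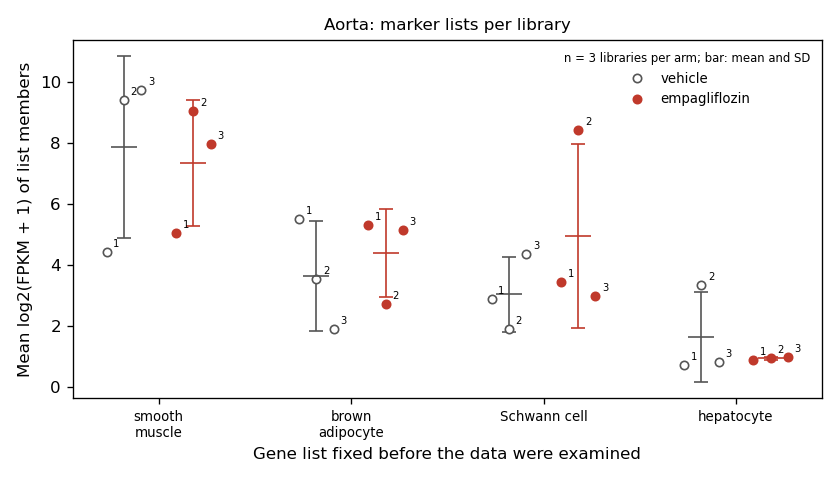
Level of 4 marker lists in each aorta library, as the mean log2(FPKM + 1) of the list members on the vertical axis and the list on the horizontal axis. Open grey circles are vehicle and filled red circles empagliflozin libraries with their replicate number, and bars give the mean and SD (n = 3); smooth muscle markers are at 4.43 and 5.05 in the libraries numbered 1 of the vehicle and empagliflozin arms.

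With limma, 0 of 13264 genes passed in aorta (smallest adjusted p = 0.999), and 146 had an unadjusted p under 0.05, 134 higher and 12 lower. The share that were higher, 91.8%, was 60.1% after median-ratio scaling. Non-overlapping arms were seen in 6.75% of genes, against 10% by chance. With all tissues in 1 fit 150 genes passed, and without the libraries numbered 1 of both arms 0 genes and 27 lists passed, against 14 lists with all libraries. The list count was 22 without vehicle library 1 and 5 without vehicle library 3.

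In brain, endothelial markers rose in 10 of 10 members (median log2 change 0.47, adjusted p = 3.09e-05) and interferon response genes in 26 of 28 (0.31, adjusted p = 5.92e-05). Among them Emcn, an endothelial sialomucin, was at 0.51 ± 0.15 (SE), and Isg15, an interferon-induced ubiquitin-like protein, at 0.90 ± 0.23. Both lists had adjusted p = 0.934 with an estimated correlation. Hypothalamus markers were at 6.01 in empagliflozin library 3 and 1.92 to 2.42 in the other 5 libraries. The interferon call was lost when a mean of at least 5 FPKM was required (adjusted p = 0.0770), and the endothelial call with all tissues in 1 fit (0.113). Without empagliflozin library 3 the medians were 0.31 for endothelial markers and 0.20 for interferon response, and the latter was 0.55 without empagliflozin library 2.

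With limma, 0 of 14000 genes passed in brain (smallest adjusted p = 0.982), and 360 had an unadjusted p under 0.05, 203 higher and 157 lower. The lowest p belonged to Nr4a3, an activity-induced nuclear receptor (-1.70 ± 0.27, SE), which fell adjusted over the immediate early list alone. Non-overlapping arms were seen in 5.92% of genes, against 10% by chance. Without empagliflozin library 2, 8 genes passed, and with all tissues in 1 fit, 168. The count of 2 lists was 4, 6 and 8 without vehicle libraries 1, 2 and 3, and 11 and 12 without empagliflozin libraries 1 and 2.

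In the libraries labelled V, cardiac stress genes fell with empagliflozin (11 of 12 members lower, median log2 change -0.34, adjusted p = 0.0292). Xirp2, an actin-binding protein of the intercalated disc, fell by 1.24 ± 0.31 (SE) adjusted over the list alone. Immediate early genes (-0.15, adjusted p = 0.0292) and glucocorticoid response genes (-0.16, 0.0292) fell as well, the latter with the metallothionein gene Mt1 at -1.13 ± 0.32. Microglia markers, which tissue macrophages share (0.43, adjusted p = 0.0364), macrophage markers (0.13, 0.0399) and fatty acid oxidation genes (0.11, 0.0430) rose. The natriuretic peptide gene Nppa was at 929.61, 760.47 and 631.52 FPKM in vehicle and at 1578.16, 1800.83 and 25.33 FPKM in empagliflozin libraries.

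Proximal tubule markers (0.87, adjusted p = 0.0292) and loop to collecting duct markers (0.77, 0.0447) rose in the libraries labelled V, in 2 of the 3 empagliflozin libraries. Kap, a kidney androgen-regulated protein, was listed at 0, 9.77 and 10.17 FPKM with empagliflozin and at 0, 0.15 and 0 FPKM in vehicle, and Umod, the tubular protein uromodulin, at 0, 3.32 and 5.23 FPKM with empagliflozin and at 0 in vehicle. With an estimated correlation the adjusted p = 0.800 for fatty acid oxidation and adjusted p = 0.760 for the other lists in these libraries. Without empagliflozin library 3 the calls of cardiac stress (adjusted p = 0.714, median 0.02), immediate early (0.0975), microglia (0.0691), macrophage (0.0852), fatty acid oxidation (0.728), proximal tubule (0.179) and loop to collecting duct (0.238) were lost. Without vehicle library 2 those of cardiac stress (0.335), glucocorticoid response (0.364), microglia (0.343), macrophage (0.343), proximal tubule (0.0678) and loop to collecting duct (0.234) were lost. Without vehicle library 3 those of immediate early (0.177), glucocorticoid response (0.132), fatty acid oxidation (0.248), proximal tubule (0.231) and loop to collecting duct (0.0973) were lost. Vehicle library 1 decided those of macrophage (0.0644), fatty acid oxidation (0.404) and loop to collecting duct (0.167), empagliflozin library 1 those of immediate early (0.0581), microglia (0.288) and macrophage (0.602), and empagliflozin library 2 those of proximal tubule (0.195) and loop to collecting duct (0.216). Quantile normalization ended the calls of fatty acid oxidation (0.0855) and loop to collecting duct (0.0660), and median-ratio scaling that of fatty acid oxidation (0.0502). Where calls stayed, the cardiac stress median was -0.52 and -0.62 without empagliflozin libraries 1 and 2, that of proximal tubule 1.33 without empagliflozin library 1 and that of macrophages 0.37 without empagliflozin library 2. The glucocorticoid median was -0.29 and -0.30 without vehicle library 1 and empagliflozin library 3, and the immediate early median -0.32 without vehicle library 2. With all tissues in 1 fit the calls of fatty acid oxidation (0.121), immediate early (0.324), microglia (0.166) and macrophage (0.131) were lost, and with a mean of at least 5 FPKM those of fatty acid oxidation (0.109), cardiac stress (0.0712), microglia (0.0552) and macrophage (0.0712), while the immediate early median was -0.24. A pseudocount of 0.1 ended the loop to collecting duct call (0.0623) and put the proximal tubule median at 2.26. Without a filter on low values the immediate early call was lost (0.0521), and the medians of proximal tubule and loop to collecting duct were 0.20 and 0.31.

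With limma, 1 of 11771 genes passed in the libraries labelled V. LOC100912534, named here after its values were seen, was listed at 13.78, 12.52 and 14.98 FPKM in vehicle and at 0 in all empagliflozin libraries (adjusted p = 9.58e-06), and is also among the 20 alternating genes. At an unadjusted p under 0.05 there were 477 genes, 202 higher and 275 lower. Non-overlapping arms were seen in 9.07% of genes, against 10% by chance. The count was 3 without vehicle library 1, 2 without vehicle library 3, 19 without empagliflozin library 1 and 4 with all tissues in 1 fit. The count of 8 lists was 3 without vehicle library 2, 4 without empagliflozin library 3 and 2 with a mean of at least 5 FPKM.

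Whether the effect of empagliflozin differed between tissues was tested as an arm by tissue term in 1 limma model over the 42 libraries of the 7 tissues with both arms. Of 16822 genes, the change in a tissue differed from the mean of the other tissues in 422 cases: 134 in kidney, 124 in lung, 82 in brain, 63 in white fat, 16 in aorta, 3 in the libraries labelled V and 0 in brown fat. Scd differed in white fat by 3.20 (adjusted p = 0.00396), but not past the threshold with a pseudocount of 0.1 (0.0578) or without the empagliflozin libraries numbered 2 (0.0910) or 3 (0.187). At the level of lists, the difference passed with an estimated correlation for 5 lists. In white fat these were lipogenesis (median difference 0.79, adjusted p = 0.0357), mesothelial markers (2.00, 0.0357) and adrenal cortex markers, called higher although their median difference was -0.048 (0.0357). In lung they were cell cycle genes (-0.92, adjusted p = 0.0340) and mesothelial markers (1.42, 0.0340). With a pseudocount of 0.1 all 5 were lost (adjusted p = 0.0697, 0.136, 0.136, 0.0616 and 0.0616). Lipogenesis was kept without the vehicle libraries numbered 1 (0.00343) and lost without the vehicle libraries numbered 2 (0.138) or 3 (0.0907) and the empagliflozin libraries numbered 1 (0.0886), 2 (0.194) or 3 (0.0575). The cell cycle list was kept without the vehicle libraries numbered 3 (0.00407) and lost without those numbered 1 (0.135) or 2 (0.177) and the empagliflozin libraries numbered 1 (0.0693), 2 (0.144) or 3 (0.126). White fat mesothelial markers were kept without the vehicle libraries numbered 1 (0.0173) and lost without those numbered 2 (0.0712) or 3 (0.0907) and the empagliflozin libraries numbered 1 (0.268), 2 (0.174) or 3 (0.0539). Adrenal cortex markers were lost in each of these 6 leave-outs (0.0764 to 0.268). Lung mesothelial markers were kept without the vehicle libraries numbered 3 (7.33e-05) and lost without those numbered 1 (0.197) or 2 (0.230), the empagliflozin libraries numbered 1 (0.0693), 2 (0.197) or 3 (0.126), and with the replicate number as a block in lung (0.0517). The gene count moved to 104 with a pseudocount of 0.1: 12 in kidney, 57 in aorta, 14 in brain, 21 in white fat and 0 in lung, brown fat and the libraries labelled V. With 1 weight per tissue it was 573, with 231 in kidney, 191 in lung, 9 in the libraries labelled V and 1 in aorta. With the replicate number as a block in lung, whose numbers were treated as pairs, it was 561, with 278 in lung.

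Leaving out a library number changed the order of the tissues in this count. Without the vehicle libraries numbered 1, 2 and 3, the total was 1891, 682 and 322, and without the empagliflozin libraries numbered 1, 2 and 3 it was 197, 1546 and 242. In the same order, kidney gave 35, 84, 45, 40, 733 and 24 genes, lung 44, 61, 240, 44, 35 and 138, and brain 21, 231, 8, 21, 385 and 17. White fat gave 46, 296, 26, 39, 39 and 18, aorta 1744, 4, 1, 38, 347 and 43, the libraries labelled V 1, 6, 2, 15, 4 and 1, and brown fat 0, 0, 0, 0, 3 and 1.

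The 3 empagliflozin atrium libraries had cardiomyocyte markers at 10.3 ± 0.20 (SD, n = 3) on the log2 scale, mesothelial markers at 3.85 ± 0.31 and smooth muscle markers at 4.79 ± 0.54. No comparison between arms was made for atrium.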

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

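The tests that weigh explanations, the splits of the libraries, the draws of the arms, the tissue weights, the leave-outs, the block in lung and the list tests with a pseudocount of 0.1 were chosen after the results were seen; the test of the difference between tissues was planned. The 23 genes and 5 lists given first differed between tissues in that test, as the log2 change in the named tissue minus the mean of the other tissues.

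In kidney the difference was 0.94 for Kcnj1, 1.76 for Klhl3, 1.76 for Aqp4, 1.13 for Top2a, 1.68 for Rplp1 and -1.91 for Ptrhd1. In white fat it was 3.20 for Scd, 2.60 for Fasn, 2.37 for Pnpla3, 2.00 for Star and -1.97 for Itgax. In lung it was 1.37 for Mcpt2, 0.96 for Muc16, 0.86 for Krt13, -2.26 for Lcn2, -0.97 for Cd8b and -1.58 for Rrm2. In aorta it was 1.94 for Ppp2r2c and 1.49 for Slc38a1, in brain -1.23 for Ndst3 and 1.83 for Pld5, and in the libraries labelled V -0.91 for Bmp10 and -1.28 for Xirp2. With a pseudocount of 0.1 only Fasn, Star, Rplp1 and Slc38a1 of these 23 genes passed, and the others, among them all those of lung, brain and the libraries labelled V, had adjusted p of at least 0.0578. With 1 weight per tissue, 0.196 in aorta, the difference was lost for both aorta genes (adjusted p = 0.9999) and for Ptrhd1 (0.0582).

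Leaving out a number in all tissues ended some of these differences. Without the vehicle libraries numbered 1, Aqp4, Top2a, Rplp1, Lcn2, Cd8b, Muc16, Krt13, Rrm2 and Xirp2 were lost (adjusted p = 0.112 to 0.435). Without those numbered 2, Aqp4, Top2a, Ptrhd1, Pnpla3, Lcn2, Cd8b, Muc16, Krt13, Rrm2, Ppp2r2c and Slc38a1 were lost (0.0507 to 0.384), and without those numbered 3, Aqp4, Top2a, Rplp1, Ptrhd1, Fasn, Itgax, Ppp2r2c, Slc38a1 and Xirp2 (0.0522 to 0.304). Without the empagliflozin libraries numbered 1, Aqp4, Top2a, Rplp1, Fasn, Pnpla3, Itgax, Lcn2, Cd8b, Krt13, Rrm2, Ppp2r2c and Slc38a1 were lost (0.0524 to 0.187). Without those numbered 2 this held for Scd, Fasn, Pnpla3, Lcn2, Cd8b, Muc16, Krt13 and Rrm2 (0.0639 to 0.220), and without those numbered 3 for Aqp4, Top2a, Ptrhd1, Scd, Fasn, Pnpla3, Itgax, Cd8b, Krt13, Rrm2 and Xirp2 (0.0565 to 0.677). Kcnj1, Klhl3, Star, Mcpt2, Ndst3, Pld5 and Bmp10 passed in all 6 leave-outs. The model shares 1 spread per gene over all tissues, so for genes expressed mainly in 1 tissue it can understate the spread there.

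Of the lists, those that passed with an estimated correlation were lipogenesis (median difference 0.79), mesothelial markers (2.00) and adrenal cortex markers in white fat, and cell cycle genes (-0.92) and mesothelial markers (1.42) in lung. Each of these lists was lost with a pseudocount of 0.1 (adjusted p = 0.0616 to 0.136) and in at least 5 of 6 leave-outs. Kept were only lipogenesis (0.00343) and mesothelial markers (0.0173) in white fat without the vehicle libraries numbered 1, and cell cycle (0.00407) and mesothelial markers (7.33e-05) in lung without those numbered 3. The adrenal cortex list was called higher, although its median difference was -0.048. Drawing the arms anew within each tissue gave at least as many genes as the real 422 in 40 of 100 draws, the real one included, and up to 8821, so chance is not excluded for this count. The lung numbers were treated as pairs. With the block in lung and the arms drawn within each lung number, 46 of 100 draws gave at least the real 561. The real one is included, the highest gave 8335, and chance is not excluded there either. The block ended the difference of mesothelial markers in lung (adjusted p = 0.0517), and the other lists and the named genes here stayed past the threshold. Draws with 8335 or 8821 genes point to a structure of the samples other than the arm. No group had the 4 libraries that a search for single outlying libraries needs.

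In kidney, podocyte and tubule transport transcripts were higher and proximal tubule transcripts lower, although with an estimated correlation the difference from the other tissues did not pass for these lists (adjusted p = 0.121, 0.121 and 0.168). A smaller share of proximal tubule and nothing else would raise the markers of every other cell type alike. Podocyte markers exceeded smooth muscle markers by a median of 1.74 ± 0.21 (SE over 6 and 8 markers). Without vehicle library 2 the smooth muscle median before centring was -0.16 instead of -0.49. The markers of a list move together and this SE holds no spread between rats, so the explanation is not excluded. Median-ratio scaling kept proximal tubule markers at -0.60 (camera, adjusted p = 0.00684), podocyte markers at 1.14 and the transport list at 0.72. A factor per library shifts a list and all other genes nearly alike. Camera compares the list with those genes, so this test cannot weigh scaling of the libraries as an explanation. Different kidney regions in the pieces stay open: the mean of podocyte and distal levels minus the proximal tubule level spanned 0.867 among vehicle libraries and 1.82 among empagliflozin libraries, against a difference of 1.45 between the arms. An effect of empagliflozin stays open too, as a hypothesis.

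In white fat, fatty acid synthesis transcripts were higher. Adipocyte markers did not rise as the list did, with a median of 0.0799 ± 0.127 (SE over 9 markers) against 1.32 for the list. This SE holds no spread between rats, so a larger share of adipocytes is not excluded. Brown fat in empagliflozin library 3 is argued against as the whole cause, since the list was still higher without that library. Its median before centring was then 0.87 (camera, adjusted p = 9.94e-15), instead of 1.15 with all libraries. Other technical causes were not tested, and a response of white fat lipid synthesis to empagliflozin remains a hypothesis.

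In the libraries labelled V, kidney transcripts were found in empagliflozin libraries 2 and 3. Kidney RNA or kidney reads in these libraries would bring every abundant kidney transcript, and 100% of 50 abundant kidney genes were above 0 in both libraries, at a median of 0.125% and 0.160% of their kidney level, which is consistent with that explanation. Over the 50 genes the log2 ratio to kidney had an SD of 0.793 and 0.687 in these libraries, so they lay near a common share of their kidney level. This argues against empagliflozin having raised these 50 genes gene by gene. Empagliflozin library 1 had 11 of the 50 above 0, within the 10 to 14 of the vehicle libraries, but 1 library excludes nothing. The kidney profile was also found without the drug, in vehicle aorta library 2 (49 of 50 genes, at 0.0949%), and in single libraries of other tissues, lung empagliflozin library 1 (47 of 50, 0.0288%) and white fat empagliflozin library 3 (42 of 50, 0.0249%).

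With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Counting the real split, as many genes as it gave were found in 10 splits in kidney (real 0, highest other 1), 10 in aorta (0 and 2241), 10 in brain (0 and 1), 2 in brown fat (1 and 2), 2 in white fat (1 and 1), 10 in lung (0 and 2) and 7 in the libraries labelled V (1 and 1). The aorta split with 2241 genes set vehicle library 1 and empagliflozin libraries 1 and 3 against the others. These 3 had the highest brown adipocyte marker levels among the aorta libraries, so the split follows that level and not the arm. Splits with as many genes at an unadjusted p under 0.05 (limma) numbered 2 in kidney (real 1504, highest other 3134). They numbered 7 in aorta (146 and 4654), 6 in brain (360 and 1363) and 6 in brown fat (419 and 1571). In white fat there were 2 (1106 and 1586), in lung 3 (1079 and 1897) and in the libraries labelled V 6 (477 and 1242). In each tissue a split off the arms thus gave more such genes than the arms. As many lists were found in 4 splits in kidney (15 and 19), 8 in aorta (14 and 26), 10 in brain (2 and 15), 7 in brown fat (9 and 18), 5 in white fat (16 and 22), 4 in lung (17 and 21) and 9 in the libraries labelled V (8 and 14). In lung, whose numbers were treated as pairs after seeing the data, 4 splits part all 3 pairs, the real one included. The others of these gave at most 0 genes and 13 lists, and 4 splits are too few to weigh chance.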

How the results depend on the processing

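The list tests under other settings than the block, fry and an estimated correlation, the aorta without the libraries numbered 1, the library weights, the block in lung and leaving out a number in all tissues were chosen after the results were seen; the other settings were planned. Of 81 list calls, 22 kept call and direction under every setting other than an estimated correlation and fry. Those settings gave 0 lists in each of the 7 tissues. For named genes, 2526 of 2692 values without 1 library and 3554 of 3621 under other settings kept direction and side of the threshold. For called lists this held for 367 of 484 and 493 of 577. The main fits called 1 gene in each of brown fat, white fat and the libraries labelled V, and 0 in the other tissues. For genes these shares thus mostly count values that passed neither before nor after, and they show no robustness of calls. With all tissues in 1 fit, 209 genes passed in kidney, 150 in aorta, 168 in brain, 0 in brown fat, 121 in white fat, 213 in lung and 4 in the libraries labelled V. With a mean of at least 5 FPKM, 0 genes passed in white fat, 1 list in brain and 2 lists in the libraries labelled V. Quantile normalization gave 11 lists in brain. Leaving out the aorta libraries numbered 1 gave 27 lists. The difference between tissues passed in 104 genes with a pseudocount of 0.1, 52 of them shared with the 422. By median, cardiomyocyte exceeded hepatocyte markers by 11.17 in the libraries labelled V. The cause was not tested for any of these.

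With the replicate block, 0 genes passed in white fat and 5 lists in brain. In the tissues other than lung the numbers were not taken as pairs: 1 kidney library and 2 of 6 in each other tissue correlated best with their own number. In the tests of single tissues the block moved no other count of calls by over 1.5 times. It ended the list calls of glycolysis in kidney (adjusted p = 0.0550) and cell cycle in aorta (0.0673). In the difference between tissues, the block in lung moved the lung count from 124 to 278 genes.

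Without 1 library at a time, 0 to 636 genes passed in kidney, 0 to 0 in aorta, 0 to 8 in brain, 1 to 3 in brown fat, 0 to 4 in white fat, 0 to 51 in lung and 1 to 19 in the libraries labelled V. The number of lists that passed was 8 to 22 in kidney, 5 to 22 in aorta, 2 to 12 in brain, 8 to 15 in brown fat, 13 to 22 in white fat, 13 to 20 in lung and 3 to 11 in the libraries labelled V, and the difference between tissues in 197 to 1891 genes. List tests that turned direction had uncentred medians of 0.0948 to 1.77 for lipolysis, -0.86 to 0.31 for macrophages and -0.11 to 2.52 for Schwann cells in aorta, -0.24 to 0.0318 for ribosomal proteins and 0.0106 to 0.30 for interferon response in brown fat, -0.20 to 0.49 for ribosomal proteins in white fat and -0.62 to 0.0209 for cardiac stress in the libraries labelled V. Ribosomal proteins in brown fat also turned under quantile normalization (0.0052). The cause was not tested. Absolute depth is unknown, and the alternatives for a file with a single unmatched library were not run, as none was used here.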

Other observations

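The genes here were chosen after their values were seen, and all tests are those of the planned fits. In kidney, members of lists that were not called passed adjusted over the list alone, among them Calb1, a calcium-binding protein of the distal nephron, which rose by a relative log2 change of 2.96 ± 0.60 (SE). In white fat Enpep, an aminopeptidase that cleaves angiotensin II, rose by 1.84 ± 0.30 adjusted over the list of its pathway alone.

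In the libraries labelled V, Myl7, an atrial myosin light chain, was at 35.70, 28.39 and 24.40 FPKM in vehicle and at 11.17, 1.13 and 0.87 FPKM in empagliflozin libraries, and fell adjusted over the cardiomyocyte list alone. Bmp10, a growth factor of the atria, was at 1.49, 0.99 and 0.98 FPKM and at 0.29, 0.21 and 0 FPKM. Neither passed over all genes in the test of this tissue alone (adjusted p = 0.999 for both, limma). Bmp10 passed with all tissues in 1 fit (-0.88, adjusted p = 4.72e-05). Its change differed from that of the other tissues (-0.91, adjusted p = 2.04e-05) except with a pseudocount of 0.1 (0.206). Both fits share 1 spread per gene over all tissues, so these p do not measure the spread between rats in the libraries labelled V. Without empagliflozin library 1, Myl7 was at -3.92 and passed (adjusted p = 0.000316). No list of atrial genes was tested, and Nppa, at 68778, 82195 and 27401 FPKM in the atrium libraries, was higher in 2 of 3 empagliflozin libraries labelled V than in the vehicle libraries.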
